A study of Mus musculus with 7 samples.

How the data were processed

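RNA from mouse mammary gland cells was measured on Affymetrix mouse expression arrays. Per the labels, 3 arrays carry side population cells (SP, the cells that exclude the Hoechst dye), 3 carry non-side population cells (NSP) and 1 carries a universal mouse reference RNA. The series' design text, a label of the submitters, states 4 replicates of each sorted population with 2 chips removed as outliers, 2 rounds of amplification of the RNA, and 2 reference chips, of which 1 is analysed here. No label says whether the sorts came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

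The deposited value table holds a linear signal intensity for each of 45101 probe sets per array, made with MAS5 per the submitters' processing notes, with the version and the scaling not given in the sources used here. The median signals of the 7 arrays lay between 79.3 and 97.2, within 1.23 times of each other, so the intensities were used as deposited. The authors' deposited comparison tables give dChip values on a log scale, group differences and present calls in percent for 1632 probe sets, with nested lists of 771, 335 and 90. Per the file headers, the authors chose them by the p-value of a paired t-test on dChip values (at most 0.05, or 0.01 for the list of 90), a minimum difference of 0.185, 0.4 or 0.7 (0.7 for the list of 90 too), and present calls in at least 20 percent of the arrays of each group. The score the authors deposited beside each p-value is the paired test's statistic. The file headers do not give the base of the logarithm. Over 1147 bright probe sets the deposited differences had 0.952 times the SD of log2 signal differences, where natural logs would give 0.693, so they were read as log2. The minimum differences then equal 1.14-fold, 1.32-fold and 1.62-fold, while the deposited lists are titled 1.2-fold, 1.5-fold and 2-fold. Read as natural logs they would equal 1.20-fold, 1.49-fold and 2.01-fold, which match the titles. The titles and the SD thus point to different bases, and log2 remains a reading.

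Gene names came only from the deposited lists, matched to a gene table of the mouse assembly GRCm38.p6. The match was by gene number for 1384 probe sets, by a gene number in the description for 51 and by a symbol there for 48. Of the 1632 probe sets, 1483 had 1 current symbol (1311 genes), 19 had several and 130 had none. The other 43405 probe sets are unnamed here. Every named gene was therefore one that the authors had listed as differing on these same arrays, and counts of direction among named genes are not independent evidence of that direction. For a gene with several listed probe sets, the one with the highest mean was used.

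Signals under the pooled 20th percentile of the 6 sorted-cell arrays (17) were set to it, log2 was taken, and the 38115 probe sets above that floor on at least 3 of the 6 arrays were tested with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided), with 64 control probe sets left out. Adjusted p-values are Benjamini-Hochberg values from limma with a threshold of 0.05. Differences are SP minus NSP on the log2 scale, ± the moderated standard error, with 3 arrays per group. A total of 34 gene lists (559 genes, 120 of them named) was fixed before the data were examined. The 11 lists with at least 5 named members were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other named genes. The list of skeletal muscle genes and that of granulocyte and activated myeloid genes were written after values had been seen. A list of mitosis genes, also written then, mostly from genes already seen, was dropped as circular. Of single-value comparisons, 3'/5' ratios of the control probe sets were tested with an exact permutation test. Named were changed genes with 1 symbol and the same direction in every pair (at most 10 each way, of which there was 1, Tph1), up to 4 members of smallest p per list described, and 15 genes fixed in advance. Of these, Ly6a, Krt18, Esr1, Pgr, Tert, Pecam1 and Col1a1 were not analysed here for want of a name in the tables used. 1 gene that the rule names is not reported here. A gene outside this rule is said to be so.

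The numbers of the samples pair them: the labels give 2 of the 3 pairs a shared day, and the file headers show that the authors compared them as pairs. Deviations from the group means correlated at 0.039, 0.041 and 0.12 across probe sets within pairs, and every sample correlated best with its own number. The comparison was planned without the pairs as a block, on the reading that the authors' comparison was unpaired, and was kept so, with the block as an alternative. Alternatives covered normalization, floor, filter, variance model, test, list test and leaving out each array. The block with an intensity trend, the paired t-test, the dChip values, Fisher's test, the 3'/5' covariate and the alternatives for the ratio were added after the data were seen.

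The method was tested on simulated data from the real means and spreads of the 38115 probe sets, in 5 runs with 200 changed each. limma recovered 0.4% of probe sets changed 2-fold, 33.2% of those changed 4-fold and 50.0% of those changed 8-fold, with 15 false calls in all runs. With an intensity trend these were 14.8%, 42.8% and 52.8%, with 8 false calls. A list of 10 of the 1311 named genes shifted by 0.5 was found in 20 of 20 runs, with 2 of 200 unshifted lists called. Those simulated genes were independent of each other, and the unshifted ones had no difference between the groups. The real named genes were all selected as differing, so these rates may not carry over to them. The number of arrays limits the precision.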

Results

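Expression was profiled in side population (SP) and non-side population (NSP) cells sorted from the mouse mammary gland by Hoechst dye fluorescence, with 3 arrays of each, and 1 array of reference RNA. SP cells pump the dye out and are studied as a source of stem-like cells. Arrays of 1 group correlated at 0.944 to 0.948 (SP) and 0.940 to 0.950 (NSP), and SP and NSP arrays of the same number at 0.929 to 0.954. The reference array correlated with the sorted cells at 0.880 to 0.891. These are correlations across probe sets, which are not independent replicates.

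The comparison of SP with NSP cells asks which genes distinguish the dye-excluding cells. Signals were higher in SP cells for all 13 named endothelial and all 16 named cell division genes, and lower for all 6 basal, 7 luminal and 10 junction genes named. These 5 lists passed camera, the endothelial one alone also with an estimated correlation (adjusted p = 0.0293; 0.178 to 0.309 for the other 4), and none of their members passed over all probe sets. Tph1, which encodes the enzyme that starts serotonin synthesis outside neurons, fell by 2.30 ± 0.16 on the log2 scale in SP cells (4.92-fold higher in NSP, limma adjusted p = 0.0451), with the same direction in 3 of 3 pairs. In the authors' deposited table its difference was -1.33. Its call was lost with the sample number as a block (0.376), with 1 array left out (0.150 to 0.179), after quantile normalization (0.0586) or centring (0.0599), and with an offset in place of the floor (0.0690).

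Tph1 was the 1 named gene among 6 of 38115 probe sets past the threshold, of which 1 was higher and 5 were lower in SP cells. The 1 that was higher has no name here and differed by 2.58 ± 0.16 (adjusted p = 0.0342), with 2 NSP arrays at the floor. The lowest, also unnamed, differed by -5.56 ± 0.35 (adjusted p = 0.0342) and lay at the floor on 1 SP array, so the sizes of both differences depend on the floor. The same holds for an unnamed probe set at -4.05, with 2 SP arrays at the floor. Another unnamed one, at -2.29, lay there on all 3 SP arrays, so its SP spread of 0 and its p-value depend on the floor too. At an unadjusted p under 0.05 there were 3324 probe sets, against 1906 by chance. With the sample number as a block limma called 0 (3758 at an unadjusted p under 0.05). With an intensity trend it called 381 (134 higher, 247 lower), and with both 942 (443 higher, 499 lower). All 6 probe sets were among these 381 and these 942. No probe set passed when any 1 of the 6 arrays was left out.

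All genes named in the lists had been listed by the authors as differing on these arrays. The counts of direction and of members that passed are therefore not independent evidence. Camera compares a list with the other named genes. It also passed up to 5 lists when the arrays were split across the populations (7 for the real split). The genes of the sort were examined first. All 4 named drug efflux transporters had higher signals in SP cells in all 3 pairs, with a median of 1.09, and 2 passed when adjusted over the list alone. Abcb1a, a P-glycoprotein gene, differed by 1.52 ± 0.18 (2.87-fold, adjusted p = 0.0777, and 0.000572 with an intensity trend). Its paralog Abcb1b was 2.30-fold higher with an SE of 0.52 on the log2 scale (adjusted p = 0.598). The log2 difference of Abcb1b ranged from 0.66 to 1.62 over the alternatives, and its NSP signals were 947, 1434 and 377. Abcg2, whose product exports the Hoechst dye, differed by 0.48 ± 0.21 (1.40-fold, adjusted p = 0.591). None passed over all probe sets tested. With the sample number as a block and an intensity trend together, an alternative chosen after the data were seen, all 4 passed (Abcb1a 0.000186, Abcb1b 0.00688, Abcc4 0.00730, Abcg2 0.0183), and with the block alone none did.

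**Figure D1:**
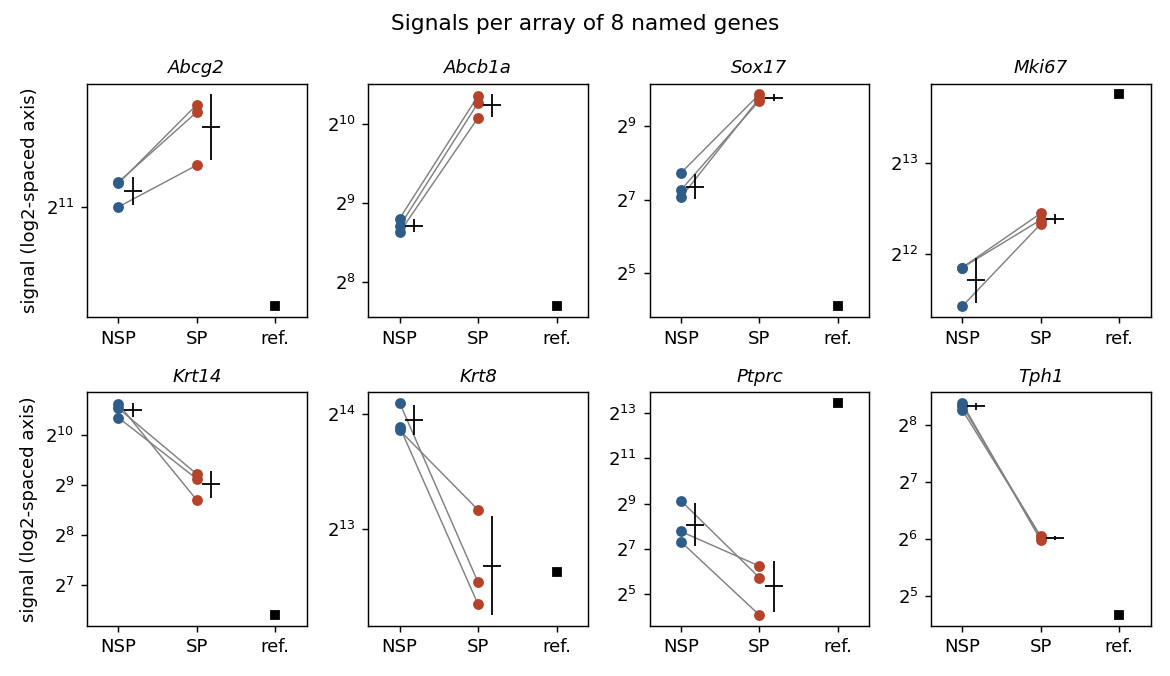
Signals of 8 named genes on a log2-spaced axis for the 3 NSP arrays (blue), the 3 SP arrays (red) and the reference RNA array (black square), with grey lines joining samples of the same number and crosses giving the mean ± SD of log2 signals (n = 3). Abcb1a signals were 397 to 447 in NSP and 1082 to 1311 in SP cells, and Tph1 signals 306 to 332 and 63.2 to 66.3.

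Endothelial markers stood highest in SP cells. All 13 named members of the list of 22 were higher, in all 3 pairs, with a median difference of 1.45 (2.74-fold). Sox17, an endothelial transcription factor, differed by 2.43 ± 0.23 (adjusted p = 0.0552), Aplnr, the apelin receptor, by 1.85 ± 0.19 (0.0622), Esam by 1.45 ± 0.21 (0.104) and Plvap by 1.45 ± 0.22 (0.113). The list passed camera (adjusted p = 1.29e-09; adjusted p = 0.0293 with an estimated correlation). None of the 13 passed over all probe sets tested, 10 did with an intensity trend, and 13 did when adjusted over the list alone.

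Of 6 named genes on a list of haematopoietic stem cell genes, 5 were higher, with a median of 0.82. Mecom differed by 1.80 ± 0.27, Tek by 1.87 ± 0.36 and Cd34 by 1.09 ± 0.19, whereas Itga6 differed by -0.57 ± 0.19. Tek and Cd34 also stand on the endothelial list. The list passed camera (adjusted p = 0.0201; adjusted p = 0.335 with an estimated correlation), and 5 members passed when adjusted over the list alone.

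Cell division genes were higher in SP cells by smaller amounts. All 16 named members of the proliferation list were higher, 15 of them in all 3 pairs, with a median of 0.51 (1.43-fold). Top2a, the DNA topoisomerase of dividing cells, differed by 0.91 ± 0.26, Aurkb by 0.88 ± 0.17, Mki67 by 0.67 ± 0.20 and Aurka by 0.66 ± 0.20. The list passed camera (adjusted p = 6.68e-05; adjusted p = 0.273 with an estimated correlation). None passed over all probe sets and 1 passed when adjusted over the list alone.

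All 5 named Notch pathway genes were higher, with a median of 0.54 (camera adjusted p = 0.0358; adjusted p = 0.309 with an estimated correlation). Notch4 differed by 1.94 ± 0.65 with 1 NSP array at the floor, Nrarp by 0.85 ± 0.31, Hes1 by 0.54 ± 0.29 and Hey1 by 0.47 ± 0.23, and none passed when adjusted over the list alone. The call was lost without SP replicate 3 (0.0658) and without NSP replicate 1 (0.0765).

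Genes of the basal and luminal epithelial lists were lower in SP cells. All 6 named basal markers were lower in all 3 pairs, with a median of -1.55 (camera adjusted p = 0.000209; adjusted p = 0.178 with an estimated correlation), and 6 passed when adjusted over the list alone. Trp63, the basal transcription factor, differed by -2.42 ± 0.32, Krt5 by -1.62 ± 0.25, Krt17 by -1.61 ± 0.26 and Krt14 by -1.49 ± 0.22. All 7 named luminal markers were lower in all 3 pairs, with a median of -1.48 (camera adjusted p = 0.000209; adjusted p = 0.309 with an estimated correlation), and 7 passed when adjusted over the list alone. Among them Cldn4 differed by -1.71 ± 0.26, Cldn3 by -1.60 ± 0.34, Cdh1 (E-cadherin) by -1.55 ± 0.27 and Krt8 by -1.27 ± 0.26. A list of luminal secretory progenitor genes had 2 named members that moved both ways, Lcn2 (-0.99 ± 0.44) and Hey1 (0.47 ± 0.23).

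All 10 named junction and adhesion genes were lower, with a median of -1.65 (camera adjusted p = 1.94e-06; adjusted p = 0.178 with an estimated correlation), and 9 passed when adjusted over the list alone. The laminin genes Lamb3 (-2.29 ± 0.20) and Lama3 (-2.24 ± 0.28) were among them, with Itgb6, an integrin subunit (-3.15 ± 0.35). In this list 3 members also stand on the luminal list.

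The leukocyte and macrophage lists had 3 named members each, too few for camera, with 1 shared. Of these 5 genes, 4 had lower signals in SP cells. Laptm5 differed by -4.91 ± 0.87, Ctss, a lysosomal protease of macrophages, by -3.81 ± 0.47, Ptprc (CD45) by -2.72 ± 0.70 and Cd68 by -0.96 ± 0.24. Ptprc lay at the floor on 1 SP array. Lcp1 differed by 0.014 ± 0.60 and changed sign under other settings. All 3 named fibroblast genes were higher, with Dcn at 1.01 ± 0.20, Col1a2 at 0.82 ± 0.26 and Pdgfra at 0.23 ± 0.27. Both named pericyte genes were higher (Abcc9 0.85 ± 0.33, Rgs5 0.45 ± 0.24), and all 3 named Schwann cell genes were lower, Cnp by -0.89 ± 0.27. None of the genes in this paragraph passed over all probe sets. Of the 3 Schwann cell genes, 1 passed when adjusted over the list alone.

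**Figure D2:**
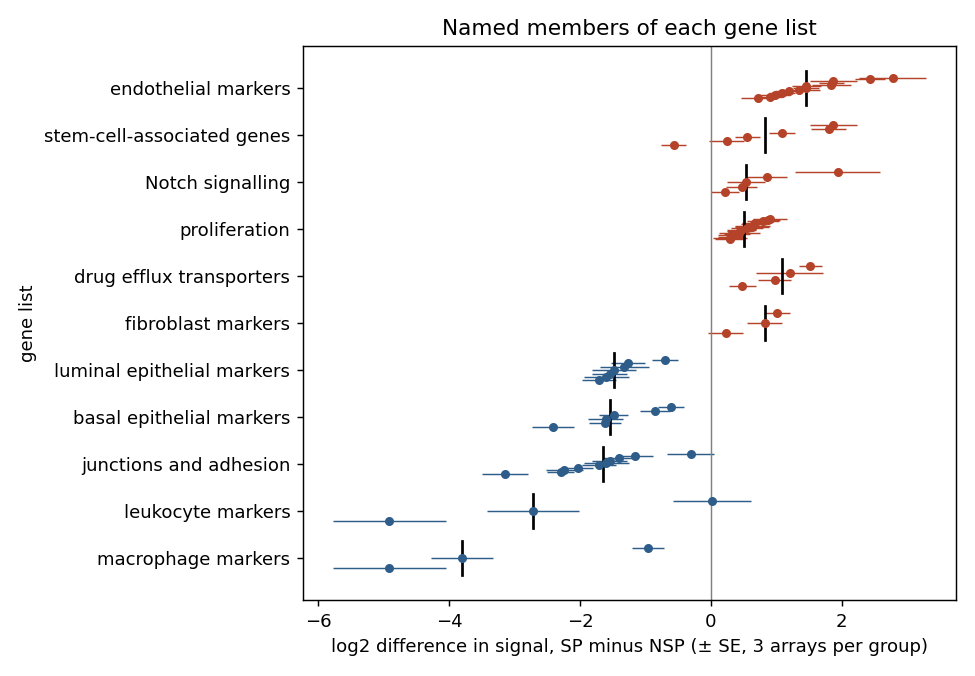
Log2 difference in signal, SP minus NSP, of each named member of 11 gene lists (points, ± SE, 3 arrays per group), with a black bar at each list's median and red or blue for a median above or below 0. The median was 1.45 for endothelial markers and -1.55 for basal epithelial markers, and all members shown were genes the authors had listed as differing.

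With an intensity trend alone, members past the threshold over all probe sets numbered 10 of 13 endothelial, 3 of 6 stem cell and 2 of 16 proliferation genes. They numbered 0 of 5 Notch, 4 of 6 basal, 6 of 7 luminal and 9 of 10 junction genes. With the block and the trend together, members past the threshold over all probe sets numbered 13 of 13 endothelial, 5 of 6 stem cell, 6 of 16 proliferation, 1 of 5 Notch, 4 of 6 basal, 7 of 7 luminal and 9 of 10 junction genes. The numbers were 2 of 3 on each of the leukocyte and macrophage lists, and 1 on each of the fibroblast, pericyte and Schwann cell lists. The fit with the block and the trend was chosen after the data were seen. Of all 1632 listed probe sets, 456 passed it, and 210 passed with the trend alone. The authors had selected these genes by pairs on the same arrays, so passing a fit with the pairs as a block is partly built in.

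The lists for DNA repair, lipid synthesis, TGF-beta and BMP signalling, and Wnt signalling did not pass camera (adjusted p = 0.995, 0.819, 0.869 and 0.869). Their members moved both ways, and for 3 of them signs of the median, mean and test differed: 0.14, -0.043 and up for DNA repair, 0.15, -0.070 and up for TGF-beta and BMP, -0.015, -0.046 and up for Wnt signalling. Lists of B cell, T cell, erythroid, hormone-sensing luminal, milk secretion and ribosomal protein genes had no named member.

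A measure of how far the amplified copies reach towards the 5' end lay beside all of these lists. The log2 ratio of 3' to 5' control signal for Actb was 3.85 ± 0.50 in SP and 3.28 ± 0.80 in NSP samples (SD, n = 3; exact permutation p = 0.5, two-sided). For Gapdh it was 3.65 ± 0.66 and 2.87 ± 0.64 (exact permutation p = 0.3, two-sided). After Benjamini-Hochberg adjustment over the 4 ratios tested both were 0.5, and the smallest p that 3 against 3 arrays can give is 0.1. The ratio was higher in SP in 3 of 3 pairs for both genes.

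The authors' deposited lists held 751 probe sets higher in SP and 881 higher in NSP cells among 1632. The signals gave 1570 of the 1632 the same direction (96.2%, 95% Clopper-Pearson interval 95.2 to 97.1), and across probe sets the differences correlated at 0.939 (Pearson) and 0.912 (Spearman). For the list of 335 it was 333 (99.4%). These shares come from the same arrays and are no independent test. The interval treats the probe sets as independent, which they are not. Without NSP replicate 3 the share was 94.4%, outside the interval. Of the 1632, 1 passed limma after adjustment, 210 with an intensity trend and 456 with the block and the trend. The authors' own conditions used an unadjusted paired p. On the signals, a paired p of at most 0.05 and a difference of at least 0.4 were met by 2002 probe sets. Of these, 400 were on the authors' list for that difference, the second largest. Of that list, 421 probe sets had a paired p of at most 0.05 on the signals, so many did not. The authors' deposited table gave median false discovery rates of 9.4%, 3.4%, 0% and 0% for its 4 lists, with 90th percentiles of 100% in each, from 50 permutations.

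**Figure D3:**
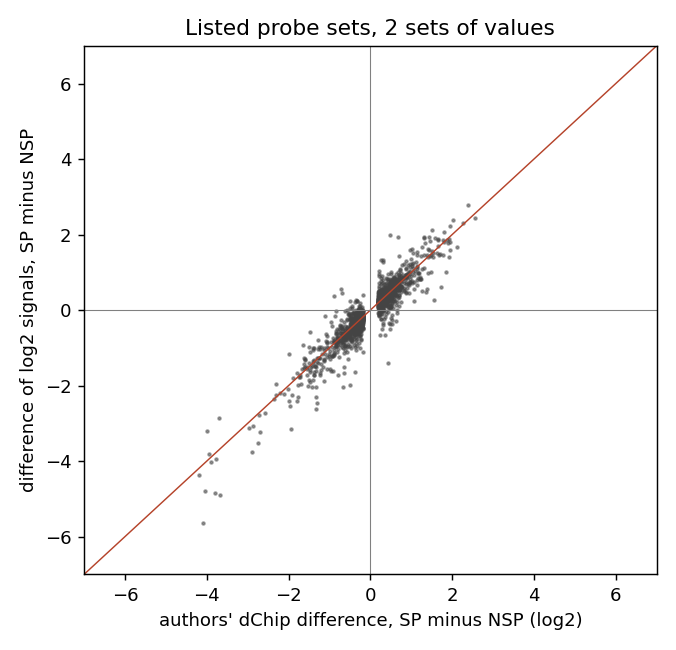
Difference of log2 signals, SP minus NSP, against the authors' dChip difference (read as log2) for the 1632 listed probe sets. Each is 1 point, and the line of equal values is red. Of the points, 1570 lie on the same side of 0 on both axes.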

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

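The replicate block, normalization, floor, filter, variance model, array weights, thresholds, plain unpaired t-test, estimated correlation, fry, the mean over the probe sets of a gene and leaving out arrays (not for the 3'/5' ratios) were planned; the other alternatives were chosen after the data were seen, and the cause of a move was not tested unless stated. Against 6 changed probe sets (1 higher and 5 lower in SP, 1 of them on the authors' lists), limma called 0 (0 higher, 0 lower, 0 listed) after quantile normalization, with an offset of 16 in place of the floor, with the replicate block and without each array in turn (0 to 0), with 3452, 3408, 3758 and 2916 to 3457 at an unadjusted p under 0.05. It called 3 after centring on the median (0 higher, 3 lower, 0 listed), 24 with the floor at the 10th percentile (11 and 13, 2 listed), 25 with it at the 40th (5 and 20, 5 listed), 32 with no filter (16 and 16, 5 listed) and 15 above the floor on all 6 arrays (6 and 9, 10 listed). It called 227 among the stated 16744 probe sets of highest mean (83 and 144, 144 listed), where fewer were tested, 381 with an intensity trend (134 and 247, 210 listed) and 942 with the block and the trend (443 and 499, 456 listed). At an adjusted p under 0.10 there were 129 (46 and 83). The plain unpaired t-test gave 2932, 2101 and 1254 at an unadjusted p under 0.05 with folds of 1.2, 1.5 and 2, and 15 after Benjamini-Hochberg. The paired t-test gave 2002 with a difference of 0.4, and 0 after Benjamini-Hochberg.

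Of the 8 genes fixed in advance and named, 0 passed, against 1 with the floor at the 40th percentile, 1 with no filter, 4 among the stated 16744, 5 with an intensity trend, 8 with the block and the trend, and 8 on the dChip values, where the probe sets had been selected. The share of listed probe sets with the same direction (96.2%) was 97.4% among the stated 16744 and 94.4% to 95.6% with 1 array left out.

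Of 7 lists past the threshold, 1 held with an estimated correlation, the endothelial one. The others then had adjusted p of 0.178 (basal), 0.335 (stem cell genes), 0.178 (junctions), 0.309 (luminal), 0.309 (Notch) and 0.273 (proliferation). The Notch call was also lost above the floor on all 6 arrays (0.0892), among the stated 16744 (0.0896), on the dChip values (0.0710) and with 1 array left out (range 0.0132 to 0.0765). Fisher's test of direction ended the basal (0.0669) and stem cell (0.149) calls. Lists that did not pass turned direction without passing: DNA repair above the floor on all 6 arrays (0.988), with fry (0.584) and with 1 array left out (0.883 to 0.995), TGF-beta and BMP with the 3'/5' covariate (0.925) and with 1 array left out (0.747 to 0.980), and Wnt with Fisher's test (1). The replicate block changed no other call of a list. Over all alternatives but the estimated correlation the endothelial adjusted p lay between 5.75e-10 and 0.000233.

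Among named genes, the gene Lcp1 turned sign with the floor at the 40th percentile (-0.090), the offset (-0.029), array weights (-0.0075) and with 1 array left out (-0.48 to 0.70). The 3'/5' ratios were higher in SP under each alternative run. Signals near the floor limit the size of differences of dim probe sets.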

Other observations

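The tests of explanations in this part, the 3'/5' covariate included, the lists of muscle and granulocyte genes and the count of splits with an intensity trend were chosen after the data were seen. Heat shock genes had higher signals in SP cells in all 4 named members, with Hspa8 at 1.30 ± 0.23, Dnajb1 at 0.67 ± 0.20, Hspa1a at 0.42 ± 0.17 and Hspa1b at 0.37 ± 0.19, and 2 passed when adjusted over the list alone. Hspa1a and Hspa1b are near-identical copies whose probe sets may not tell them apart, and their values (0.42 and 0.37) are uncertain for that reason. Both named detoxification genes were higher, Nqo1 by 1.13 ± 0.31 and Gsta4 by 1.17 ± 0.58. Both named cell cycle inhibitors were higher too, Btg2 by 0.62 ± 0.22 and Cdkn2c by 0.48 ± 0.17. None passed over all probe sets.

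Lists written after values were seen showed other groups. All 7 named genes of 40 on the skeletal muscle list were lower in SP cells in all 3 pairs, with a median of -2.21. All 12 named genes of 22 on a list of granulocyte and activated myeloid genes were lower, with a median of -2.13, and included Chil3 (-4.79 ± 0.56), Ccl6 (-4.85 ± 0.71, at the floor on 1 SP array), Arg1 (-3.76 ± 0.57) and Mmp9 (-2.22 ± 0.32). 1 of the 12 may be either of the near-identical Lyz1 and Lyz2, since its deposited gene number and description disagree. Both lists were composed with these genes in view, so their counts test nothing.

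Endothelial markers were higher in SP cells (median 1.45 over 13 genes). A lower epithelial share alone would raise markers of other cell types alike. The 5 named haematopoietic and myeloid genes instead had a median of -2.72, though Lcp1 among them differed by 0.014 ± 0.60. Their standard error over members was 0.90, a spread between genes and not between samples. The 3 named Schwann cell genes had a median of -0.89, with an SD over members of 0.92. Only 1 of these 3 passed when adjusted over the list alone. All 3 named fibroblast and both pericyte genes were higher (medians 0.82 and 0.65). A lower epithelial share alone does not account for the markers that were lower. Whether it contributes to the endothelial difference stays open, since these selected genes of other cell types moved both ways. With the 3'/5' ratio as a covariate the list kept its side of the threshold (adjusted p = 7.92e-09, median 1.47). Endothelial cells or their RNA in the SP gate may be the source: Sox17 signals were 832 to 939 in SP and 134 to 212 in NSP cells, and the sources used here name no antibody step that would remove such cells. This stays open, since 100% of the members being higher in every pair decides nothing where the authors' paired selection gave 80.5% of all 1311 named genes 1 direction in every pair, as does an endothelial-like state of the sorted cells, which was not tested.

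Skeletal muscle genes were higher in NSP cells, among them Actc1 (-3.93 ± 0.36), Ttn (-3.53 ± 0.38), Chrna1 (-2.21 ± 0.32) and Tnnt2 (-1.57 ± 0.25), of which Actc1 and Tnnt2 are better known from the heart. These 7 genes were not lower in 1 pair alone, since their median was -2.0 (standard error over members 0.53) in the pair where it was smallest. The authors' paired selection could hardly list a gene that differs in 1 pair alone, and other muscle genes were not examined. Whether muscle cells or RNA in 1 NSP preparation alone raised muscle genes in general therefore cannot be decided here. Muscle cells or RNA in every NSP preparation may be the source, and stays open because that selection makes the 100% lower in every pair uninformative. No biological explanation was tested.

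Cell division genes were higher in SP cells (median 0.51 over 16 genes). The authors' dChip processing alone does not account for it in these 16 genes, since 100% of them were higher on the MAS5 signals too, from the same arrays, as 96.2% of all 1632 listed probe sets kept their direction. With the 3'/5' ratio as a covariate the list stayed past the threshold (adjusted p = 0.000615) with a median of 0.39. A difference in cycling between the sorted populations stays open, untested, as does correlation among these genes, with which the call ended (adjusted p = 0.273).

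The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 6 probe sets and the highest of the other splits 0, and with an intensity trend 381 and 0, each reached by 1 of the 10 splits. For gene lists the real split gave 7 and the highest other split 5, so camera with the preset correlation called lists in splits that mix the populations. The real count of 7 was reached by 1 of the 10 splits, on genes that the authors chose for the real split. Among the 4 splits that part all 3 pairs, the other 3 gave 0 probe sets in each fit and 4 to 5 lists.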
